A study of Mus musculus with 10 samples.

How the data were processed

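DNA methylation was measured by whole-genome bisulfite sequencing in 10 libraries of SMARTA CD4 T cells from C57BL/6 mouse spleen, with 2 libraries in each of 5 groups: naive, effector TH1, effector TFH, memory TH1 and memory TFH cells. Per the labels, DNA was prepared with DNeasy kits, libraries with the NEBNext Ultra II kit, conversion with the EZ DNA Methylation Gold kit and paired reads on a NovaSeq instrument. Per the submitters' processing notes, reads were trimmed with Trim Galore (no version given), checked with FastQC 0.11.4 and aligned to mm10 with Bismark 0.19.0, and the names of the deposited data state that duplicate reads were removed. Each of the 10 deposited tables has 7 columns without a header. The deposited values are counts of methylated and unmethylated reads per CpG site, with their sum (the coverage) and the methylated percent. The sum was recomputed here from the counts and matched, while the deposited percent was not read. The smallest coverage in each table was 5 reads, and both strands of a CpG were listed together. Sites listed at a single base were joined to the CpG that another listing showed on both strands, and those that no library listed on both strands were left out.

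Reads over listed sites numbered 150529902 to 263504263 per library, with a median coverage of 9 to 13 at autosomal sites. Of the 19311886 autosomal CpG sites listed in any library, 9929436 were listed in all 10 and were used. Reads on the mitochondrial genome, where little CpG methylation is found, were methylated in 0.746% to 1.83%, which sets a rough upper limit on unconverted cytosines. The sexes in the labels were checked on the sites listed on the Y chromosome, 44197 to 58885 in male and 1152 to 1274 in female libraries, and all 10 matched. Tile levels correlated at 0.879 to 0.913 (Pearson, across tiles) between libraries of a group and at 0.783 to 0.897 between groups, and tiles are not independent replicates.

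The 19 autosomes were divided into adjacent tiles of 500 bp, and tiles with at least 3 of the common sites were tested, 1569537 in all with a median of 4 sites. Counts were summed per tile and fitted with a quasi-binomial logistic model with 1 level per group over all 10 libraries (5 residual degrees of freedom), written in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Numba 0.67.0. Dispersions were moderated across tiles with squeezeVar of limma 3.58.1 (trend and robust options) in R 4.3.3 and not allowed below 1; their median was 1.15. Contrasts were tested with the quasi-F test and adjusted by Benjamini-Hochberg over all tiles of a comparison. A tile was called at an adjusted p under 0.05 and a difference of group means of at least 20 points. Differences between libraries of 1 group were 1.15 to 1.21 times the binomial variance. The procedure was tested on simulated data with 200000 tiles: of simulated differences of 20, 30 and 40 points between effector TFH and TH1 cells it called 33.3%, 79% and 95.6%, 2.03% of its calls were false, and in a comparison without differences it called 0 tiles. The simulation gave every tile the same overdispersion of 1.2 and no genome-wide shift. Its share of false calls therefore does not carry over to the real calls. Figures were drawn with Matplotlib 3.10.9.

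The 6 main comparisons were effector TH1 and effector TFH against naive, TFH against TH1 in effector and in memory cells, and memory against effector in each lineage. Memory against naive and the change of the TFH-TH1 difference from effector to memory were fitted in the same model. The tile test, the thresholds, the comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Later choices were the reach of a gene on both sides, 2 alternatives (each tile's own dispersion where it was larger than the moderated one, and a coverage of at most 100) and the list tests with centred libraries. No genome sequence, gene strand or exon table of the build was available, so a gene was taken as its RefSeq span plus 5000 bp on both sides in place of 5000 bp upstream. Promoter methylation, sequence motifs, exons and introns, and matching on GC content are not analysed here.

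The 10 fixed gene lists were TH1 and cytotoxic effector, TFH, naive and central memory, other helper lineages (TH2, TH17 and regulatory T cells), activation and inhibitory receptors, DNA methylation machinery, T cell identity, B cell markers, myeloid markers, and CD8 T and NK cell markers. A few genes stand in more than 1 list, such as Pdcd1, Havcr2 and Tox. For each list the members with a called tile were counted and compared with 10000 random lists of autosomal protein-coding genes with similar numbers of tested tiles (one-sided, adjusted by Benjamini-Hochberg over the list tests of a comparison, 120 tests in the main comparisons). The smallest p these random lists can give is 0.0001 before adjustment, and they treat genes, not libraries, as units. Named genes were, per comparison, up to 6 members of each of the first 3 lists and up to 3 of each other list with the largest difference at a called tile, the 5 genes per direction outside the lists with the most called tiles, and the 3 called tiles per direction with the largest F. A fixed set of genes, among them Gzmb, Ifng, Prf1, Tbx21, Cxcr5, Bcl6, Pdcd1, Tcf7, Ccr7, Il7r, Dnmt3a and Tet2, was evaluated in every comparison whether called or not; for an uncalled gene the tile with the smallest p is given.

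Alternatives were tile width, sites per tile, coverage, the size of the difference, limma on percents and on logits, libraries centred on a common level, covariates for sex and for the number in the titles, the replicate number as a block, each library left out in turn, and fits of only the 4 libraries compared. With 1 library left out, the lone library of its group is assumed to vary like the other groups. The replicate numbers of the memory groups share a day after infection (75 or 92), while those of other groups are not stated to pair; the replicate differences correlated at 0.0108 between the effector groups and 0.00937 between the memory groups across tiles, so the model did not use the number. The X chromosome was fitted apart with sex as a covariate, and the Y chromosome was left out.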

Results

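DNA methylation was measured by whole-genome bisulfite sequencing in SMARTA CD4 T cells, which carry a transgenic T cell receptor for a peptide of lymphocytic choriomeningitis virus, sorted from mouse spleen. The 10 libraries fell into 5 groups of 2: naive cells, effector TH1 and effector TFH cells taken at day 7 after infection with the Armstrong strain, and memory TH1 and memory TFH cells taken at days 75 and 92. TH1 cells make interferon gamma and help macrophages and cytotoxic cells, and TFH cells enter B cell follicles and help B cells. Each group held 1 male and 1 female library, and replicates are counted as separate animals only as far as the labels give this. Moderation left nearly the same dispersion at every tile (5th to 95th percentile 1.12 to 1.19). Each p-value therefore measures the counting error of reads scaled by that shared value, and little of a tile's own spread between libraries. The files listed between 15188312 CpG sites (memory TFH replicate 1) and 19422843 (memory TFH replicate 2), with 150529902 to 263504263 reads over them and a median coverage of 9 to 13 reads per autosomal site. The 9929436 autosomal sites present in all 10 libraries gave 1569537 tiles of 500 bp with a median of 52 reads per tile and library. Values are methylation levels in percent as mean ± SD with n = 2 libraries per group, and differences are in percentage points. Coordinates are those of mm10. Confidence intervals are for shares of tiles. They treat tiles as independent, which tiles are not, and do not cover the spread between libraries. A called tile differed by at least 20 points with an adjusted p under 0.05 (quasi-F test with limma-moderated dispersion, Benjamini-Hochberg over all tiles, two-sided).

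Genome-wide methylation was highest in naive cells at 86.4% ± 0.569 and lowest in effector TH1 cells at 75.5% ± 0.124. Effector TFH cells stood at 81.2% ± 0.092, memory TH1 cells at 79.1% ± 0.214 and memory TFH cells at 81.7% ± 0.458. The gap between any of the 4 activated groups and naive cells was larger than the spread between replicates, although an exact permutation test of 2 libraries against 2 cannot go below p = 0.333 (two-sided). Libraries also differed in the number that opens the library code in their titles, 15105 or 15796, whose meaning the labels do not give. Within 15105, effector TH1 cells were 11.1 points and effector TFH cells 5.26 points below naive cells (-11.1 and -5.26). Effector TFH cells were 5.81 points above effector TH1 cells within 15105 and 5.76 points above them within 15796. Each of the values within a number rests on 1 library per effector group. In these groups the 15105 libraries were female and the 15796 libraries male. All memory libraries carried 15796 and both naive libraries 15105, so memory and naive cells could not be compared within a number.

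**Figure D1:**
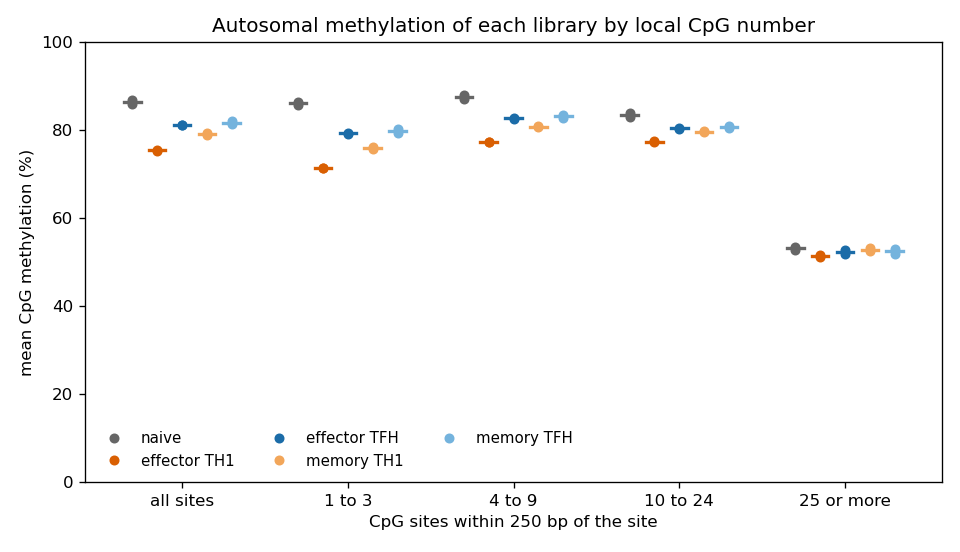
Mean methylation over common autosomal CpG sites (y axis, percent) in each of the 10 libraries (points, with group means as lines), for all sites and by the number of CpG sites within 250 bp (x axis). Over all sites naive libraries averaged 86.4% and effector TH1 libraries 75.5%.

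Effector TH1 cells were compared with naive cells to ask which loci change methylation as naive cells become TH1 cells. Stat4, which carries the interleukin 12 signal, went from 94.4% ± 3.98 in naive cells to 0% ± 0 in effector TH1 cells at the tile of chromosome 1 from 52041001 to 52041500 (-94.4 points, adjusted p 1.21e-47). Tbx21, the gene of the TH1 regulator T-bet, went from 96.4% ± 5.05 to 5.51% ± 1.64 on chromosome 11 from 97112001 to 97112500 (-90.9 points, adjusted p 1.15e-37). Ifng, the gene of interferon gamma, went from 90.3% ± 3.59 to 2.1% ± 1.08 on chromosome 10 from 118441501 to 118442000 (-88.2 points, adjusted p 1.69e-55). Tcf7, the gene of the naive and TFH factor TCF1, moved the other way, from 1.55% ± 0.0851 to 73.1% ± 1.28 on chromosome 11 from 52271001 to 52271500 (71.6 points, adjusted p 2.31e-28). All 4 lay inside the gene spans and were called with each of the 10 libraries left out in turn and after the libraries were centred on a common mean level.

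Among further TH1 genes, Il18rap (a chain of the interleukin 18 receptor) fell from 93% to 4.42%, Gzmk (a granzyme) from 94% to 6.73% and Il12rb2 (a chain of the interleukin 12 receptor) from 87.9% to 2.77%. Gzmb and Prf1, which encode granzyme B and perforin, lost less: Gzmb reached 61.1% ± 12.3 from 94.7% (adjusted p 6.01e-04) and Prf1 57.6% ± 1.29 from 83.7% (adjusted p 1.04e-03), and neither call held after centring. Several genes of the TFH list also fell in effector TH1 cells, although the list itself did not pass the test (26 of 29 genes against 22.4 in random lists, adjusted p 0.15). Icos, a costimulatory receptor, fell from 96% to 2.44% and the kinase gene Fyn from 91.4% to 0%. Il21, the cytokine that acts on germinal centre B cells, fell from 91.9% to 2.22%, Hif1a from 95.1% to 7.85% and Nfatc1, a target of receptor signalling, from 92% to 1.25%. The inhibitory receptor genes Pdcd1 and Tigit fell from 92.2% to 9.52% and from 96.8% to 8.83%, and Irf4, a factor induced by receptor signalling, from 88.9% to 9.35%. Cxcr5, the receptor that guides TFH cells to follicles, reached only 45.5% ± 8.13 from 69.6% (-24.1 points, adjusted p 3.08e-05), a call lost with centring and without effector TH1 replicate 2. Bcl6, the regulator of TFH cells, fell from 85.5% to 64% (-21.5 points, adjusted p 0.0244), a call lost with centring and without naive replicate 1, naive replicate 2, effector TH1 replicate 1 or effector TH1 replicate 2.

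Genes of naive and central memory cells gained methylation at some tiles and lost it at others. Only the gains of this list passed the test against random lists, although 19 of 24 genes held a tile called lower. Ccr7, which guides cells into lymph nodes, rose from 20.7% ± 1.81 to 65.9% ± 0.481 (45.2 points, adjusted p 1.61e-13). Il7r, the interleukin 7 receptor, fell from 91.7% to 19.5% at its strongest tile. Foxp1 held 14 tiles called higher and 103 called lower, Bach2 4 and 55, and Bcl2 2 and 23. Outside the lists the largest gains by the test were at Polr3g, a subunit of RNA polymerase III (from 3.32% to 58.4%), and Osbpl11, a lipid transfer protein (from 5.67% to 59%). The largest loss by the test was at Hivep3, a zinc finger gene, from 93.6% to 7.48% (adjusted p 7.58e-168). Of the genes of the DNA methylation machinery, 16 of 17 held a tile called lower, against 14.3 in random lists (adjusted p 0.332), and 3 held 1 called higher. Dnmt3a, a DNA methyltransferase, fell from 96.3% to 24.1%, Tet2 from 93% to 17.3%, Tet3 from 80.8% to 2.08% and Mbd2, a reader of the mark, from 97% to 14.5%.

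The comparison of effector TH1 and naive cells called 190547 of the 1569537 tiles, 187961 lower and 2586 higher in TH1 cells, against a median shift of -9.49 points over all tiles. With the libraries centred, 29474 tiles were called, of which 20188 were lower and 9286 higher, and 22774 were shared with the uncentred calls; the share called higher was 31.5% with centring and 1.36% without. All 35 tested genes of the TH1 list held a tile called lower, against 26.3 in random lists of genes with as many tiles (adjusted p 0.000667), and the number was 35 adjusted over the list alone. All 20 activation and inhibitory receptor genes did so against 15.6 (adjusted p 0.026; 20 adjusted over the list alone). Of the naive and central memory genes, 17 of 24 held a tile called higher against 3.09 (adjusted p 0.000667; 17 adjusted over the list alone), of the T cell identity genes 10 of 18 against 1.71 (10 adjusted over the list alone), and of the genes of other helper lineages 5 of 20 (adjusted p 0.0368; 5 adjusted over the list alone). These list results kept their direction with centring, where 28 TH1 genes were called lower (adjusted p 0.0004) and 20 naive and central memory genes higher (adjusted p 0.0004). The remaining lists did not pass the test: tiles called lower were held by 26 of 29 TFH genes, 16 of 17 genes of the DNA methylation machinery, 8 of 12 B cell markers, 9 of 13 myeloid markers and 11 of 12 CD8 T and NK cell markers. Nor did tiles called lower pass for 19 of 24 naive and central memory genes, 15 of 18 T cell identity genes and 17 of 20 genes of other helper lineages. With centring the TFH list passed in both directions (19 genes lower, adjusted p 0.001, and 12 higher, adjusted p 0.00657). With 20000 bp on both sides of a gene 35 TH1 and 20 activation genes were called lower, which did not pass (adjusted p 0.316 and 0.681), and with at least 30 points the 3 T cell identity genes called higher did not (adjusted p 0.058). For tiles called lower with centring, the CD8 T and NK cell markers (6 genes, adjusted p 0.0288), the T cell identity genes (13, adjusted p 0.0004) and the genes of other helper lineages (12, adjusted p 0.00844) also passed.

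Effector TFH cells were compared with naive cells to ask which loci change as naive cells become TFH cells. Cxcr5 went from 95.5% ± 0.535 in naive cells to 18.4% ± 4.97 in effector TFH cells on chromosome 9 from 44523501 to 44524000 (-77.1 points, adjusted p 1.68e-27), where effector TH1 cells stayed at 77.2% ± 1.73. Icos went from 96% to 0% (-96 points, adjusted p 1.04e-21), Il21 from 91.9% to 0% and Pdcd1 from 92.2% to 2.63%. TH1 genes lost methylation in TFH cells too: Ifng reached 10.2% ± 0.275 (-80.1 points, adjusted p 1.56e-39), Stat4 4.44% ± 2.56 and Tbx21 22.8% ± 3.99 from 89.8% (-67 points, adjusted p 1.06e-33). Lef1, a partner of TCF1 in naive cells, rose from 0% ± 0 to 70.5% ± 20.2 (70.5 points, adjusted p 2.35e-19).

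Other losses in effector TFH cells lay at Hif1a (95.1% to 0%), Fyn (91.4% to 0%), Tox, a factor of chronically stimulated and TFH cells (93.1% to 3.45%), and Bcl2, which blocks cell death (97% to 1.85%). Prdm1, the gene of BLIMP1, which opposes BCL6, fell from 95.7% to 4.3% at a tile outside the gene span, although a tile inside the gene lay far higher in TFH than in TH1 cells. The interleukin 2 receptor gene Il2ra fell from 93.1% to 17.7%, the costimulatory receptor gene Cd28 from 84.7% to 6.29%, Tigit from 96.8% to 10.4% and Il10 from 68.3% to 0%. Cd4 itself fell from 73.9% to 8.12% at a tile 254 bp from its span. Ccr7 rose from 20.7% to 70.4% ± 6.06 (49.7 points, adjusted p 9.98e-16), and 15 tiles of Lef1 were called higher and 1 lower. Tcf7 was called lower at a tile outside the span, from 94.1% to 54.4%, but not without naive replicate 2, while the inner tile that gained 71.6 points in TH1 cells stood at 12.4% ± 11.4 in effector TFH cells. Bcl6 fell from 85.9% to 56.9% (-29.1 points, adjusted p 3.27e-04), a call lost without naive replicate 1 or effector TFH replicate 1. Gzmb (18.8 points, adjusted p 0.0358) and Prf1 (16.6 points, adjusted p 0.0088) were below the 20-point minimum; both were called higher with centring, Gzmb also with the title number as a covariate (21.6 points) and Prf1 also without naive replicate 2.

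The comparison of effector TFH and naive cells called 36828 tiles, 33996 lower and 2832 higher, against a median shift of -4.14 points. With centring 18551 tiles were called, 13228 lower and 5323 higher, of which 16060 were shared; the share called higher was 28.7% with centring and 7.69% without. TH1 genes held a tile called lower in 27 of 35 cases against 14.5 in random lists (adjusted p 0.0004; 28 adjusted over the list alone), TFH genes in 22 of 29 against 12.4 (22 adjusted over the list alone) and activation genes in 18 of 20 against 8.63 (18 adjusted over the list alone). T cell identity genes were called lower in 15 of 18 cases and higher in 11 of 18, and genes of other helper lineages lower in 15 of 20 and higher in 6 of 20 (15, 12, 15 and 6 adjusted over the list alone). Naive and central memory genes held a tile called higher in 18 of 24 cases against 3.27 (18 adjusted over the list alone), TFH genes in 7 of 29 (adjusted p 0.006; 7 adjusted over the list alone) and TH1 genes in 6 of 35 (adjusted p 0.0258; 7 adjusted over the list alone). Of the lists that did not pass, tiles called lower were held by 18 naive and central memory genes, 12 genes of the DNA methylation machinery, 3 B cell markers, 4 myeloid markers and 7 CD8 T and NK cell markers. With centring the list results above passed in the same directions (22 TH1 genes lower and 20 naive and central memory genes higher), and 4 more passed. These were 9 genes of the DNA methylation machinery (adjusted p 0.0382), 5 CD8 T and NK cell markers (adjusted p 0.031) and 17 naive and central memory genes (adjusted p 0.000222) for tiles called lower, and 8 activation genes for tiles called higher (adjusted p 0.0008). With at least 30 points the TFH, TH1 and other helper genes called higher no longer passed (3, 3 and 2 genes, adjusted p 0.116, 0.116 and 0.208). Both effector groups were measured against the same naive libraries. They shared 1612 tiles called higher and 28490 called lower, against 4.67 and 4071 for independent lists. In a simulation all 10 libraries, naive ones included, were drawn from the naive levels. It shared 0 and 0 called tiles, which its lack of true differences fixed in advance, so these simulated counts do not measure the effect of shared controls. The covariance of the differences was 47.6 and the simulated one 9.83; with 2 naive libraries each side of a split would hold 1, so no split was made and part of the excess may come from these shared controls.

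**Figure D2:**
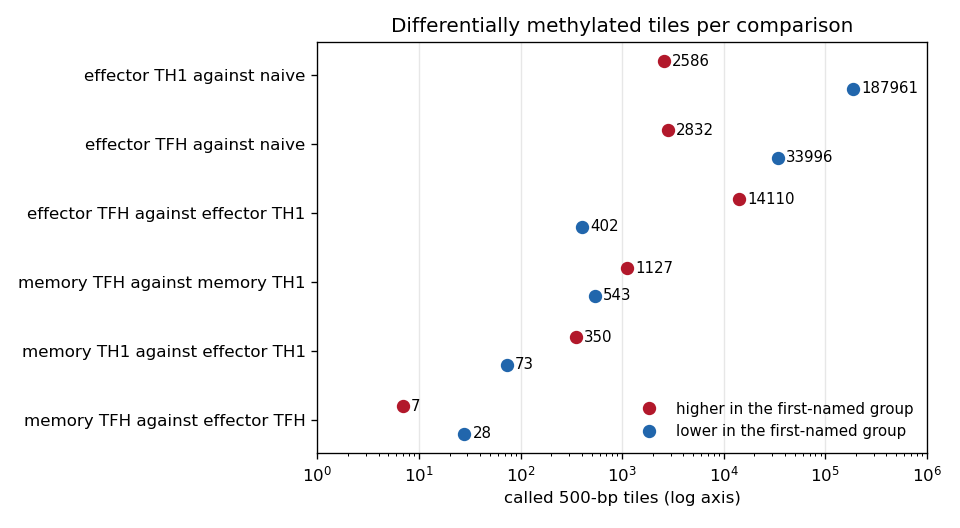
Number of called 500-bp tiles (logarithmic axis) for each of the 6 comparisons, split into tiles higher and lower in the first-named group. The effector TH1 comparison with naive cells had 187961 tiles called lower and the memory TFH comparison with effector TFH cells 28.

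Effector TFH cells were compared with effector TH1 cells to ask where the lineages differ at the peak of the response. Prdm1 stood at 16.5% ± 0.193 in TH1 and 86.6% ± 0.743 in TFH cells on chromosome 10 from 44446001 to 44446500 (70 points, adjusted p 1.68e-18), and at 28.2% ± 2.61 in naive cells. Cxcr6, a chemokine receptor of tissue-homing TH1 cells, stood at 24.2% ± 2.81 in TH1 and 84.8% ± 5.83 in TFH cells (60.6 points, adjusted p 4.42e-09). Cxcr5 stood at 77.2% ± 1.73 in TH1 and 18.4% ± 4.97 in TFH cells (-58.7 points, adjusted p 4.47e-11). Tcf7 stood at 73.1% ± 1.28 in TH1 and 12.4% ± 11.4 in TFH cells (-60.7 points, adjusted p 2.45e-15). These 4 calls held with each library left out, after centring and in both limma fits, and all but Tcf7 held with each tile's own dispersion.

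Among TH1 genes, Havcr2, which encodes the inhibitory receptor TIM3, was at 32.3% in TH1 and 89.2% in TFH cells (adjusted p 8.99e-13). A tile 107 bp from Ifng was at 13.7% and 66.7% (adjusted p 3.9e-06), and the receptor gene Ifngr1 at 20.4% and 72%. The killer receptor gene Klrd1 was at 35.1% and 84.7% (adjusted p 3.47e-07), and Il1rl1, the interleukin 33 receptor beside the interleukin 18 receptor genes, at 14.4% and 52.2%. These 5 tiles were called with centring, without each library in turn and by limma on percents. Limma on logits kept only Havcr2 and Ifng, and each tile's own dispersion did not keep Havcr2 or Klrd1. Prf1 was at 53% and 84.4% (adjusted p 6.29e-05), a call that held with centring but not without effector TFH replicate 2. Tbx21 held 8 tiles called higher in TFH cells, the strongest at 27% and 68.3% (41.4 points, adjusted p 0.0241). It was no longer called with centring or without effector TH1 replicate 1, effector TH1 replicate 2, effector TFH replicate 1 or effector TFH replicate 2. Gzmb (32.1 points, adjusted p 2.55e-03) was lost with centring and without effector TH1 replicate 1 or effector TFH replicate 2.

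Lower methylation in effector TFH cells lay at Tnfsf8, a ligand of the tumour necrosis factor family (78% in TH1 and 24.4% in TFH cells, adjusted p 9.32e-10), and Tox (35% and 1.11%, adjusted p 1.08e-05). Btla, an inhibitory receptor of TFH cells, was at 41% and 5.12% (adjusted p 1.51e-07), against 2.78% in naive cells. Outside the lists Scfd2 was at 69.8% and 24% (adjusted p 2.14e-18), Asap1, an actin regulator, at 67.6% and 17.1%, and Tspan5, a tetraspanin, at 84% and 45.1%. Lpp, whose locus neighbours Bcl6, held 15 tiles called lower and 6 called higher in TFH cells, the strongest at 68.4% and 19%. The largest value of the test was at Osbpl9, a lipid transfer protein, with 13.4% in TH1 and 72.6% in TFH cells (adjusted p 2.12e-26), followed by Vmp1 (31.2% and 72.4%) and Osbpl3 (17.7% and 61.1%). All of these tiles held with centring and with each library left out, but limma on logits kept none of them. Limma on percents did not keep Tox or Tspan5, and each tile's own dispersion did not keep Tnfsf8, Btla, Tspan5, Osbpl9 or Osbpl3. Bcl6 was higher in TFH cells at 1 tile (16.6% and 41.7%, adjusted p 0.0206), which was lost with centring and without effector TH1 replicate 2, effector TFH replicate 1 or effector TFH replicate 2. Pdcd1 was not called (-15.3 points, adjusted p 0.0655) except with centring, and Ccr7 (12 points) and Dnmt3a (11.3 points) stayed below the 20-point minimum.

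The comparison of the effector lineages called 14512 tiles, 14110 higher and 402 lower in TFH cells, against a median shift of 5.14 points. With centring 1230 tiles were called, 572 higher and 658 lower, and 965 were shared, so that 46.5% were higher with centring and 97.2% without. Without effector TFH replicate 2 the count was 3035, without effector TFH replicate 1 4281, without effector TH1 replicate 1 7388 and without effector TH1 replicate 2 6876. Limma on percents called 467 tiles and limma on logits 39. Of the 52 named called tiles, 28 were called with centring, 21 by limma on percents, 7 by limma on logits and 23 with each tile's own dispersion, and none changed direction. Of the TFH-higher tiles, 10455 (74.1%) were called lower than naive in TH1 cells alone and 7.14% in both lineages. Of the TFH-lower tiles, 37.3% were called lower than naive in TFH cells alone and 23.4% higher than naive in TH1 cells alone. Here alone means only that the other lineage was not called. The effector libraries that selected these tiles were used again against naive cells, so their chance values favour both calls. These shares therefore do not show in which lineage a difference arose.

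In the same comparison 23 of 35 TH1 genes held a tile called higher in TFH cells, against 5.09 in random lists (adjusted p 0.001; 23 adjusted over the list alone), and with centring 15 did (adjusted p 0.001). Tiles called lower in TFH cells were held by 6 of 29 TFH genes against 0.362 (adjusted p 0.001; 6 adjusted over the list alone; 9 with centring, adjusted p 0.001) and 5 of 24 naive and central memory genes against 0.674 (adjusted p 0.00333; 5 adjusted over the list alone; 5 with centring, adjusted p 0.0173). CD8 T and NK cell markers were called higher in 5 of 12 cases (adjusted p 0.005; 5 adjusted over the list alone) and activation genes in 7 of 20 (adjusted p 0.0416; 8 adjusted over the list alone), and both ended with centring (1 gene each, adjusted p 0.22 and 0.482). The activation genes did not pass with at least 30 points or with 20000 bp on both sides either (adjusted p 0.082 and 0.237). The same lists also held tiles of the other direction without passing: 6 TFH genes against 4.89 and 11 naive and central memory genes against 8.48 held a tile called higher in TFH cells, and with centring 0 of either did. The other lists did not pass: tiles called lower were held by 2 T cell identity genes (adjusted p 0.138), and tiles called higher by 6 T cell identity genes, 5 genes of other helper lineages, 2 genes of the DNA methylation machinery, 2 myeloid markers and 1 B cell marker.

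**Figure D3:**
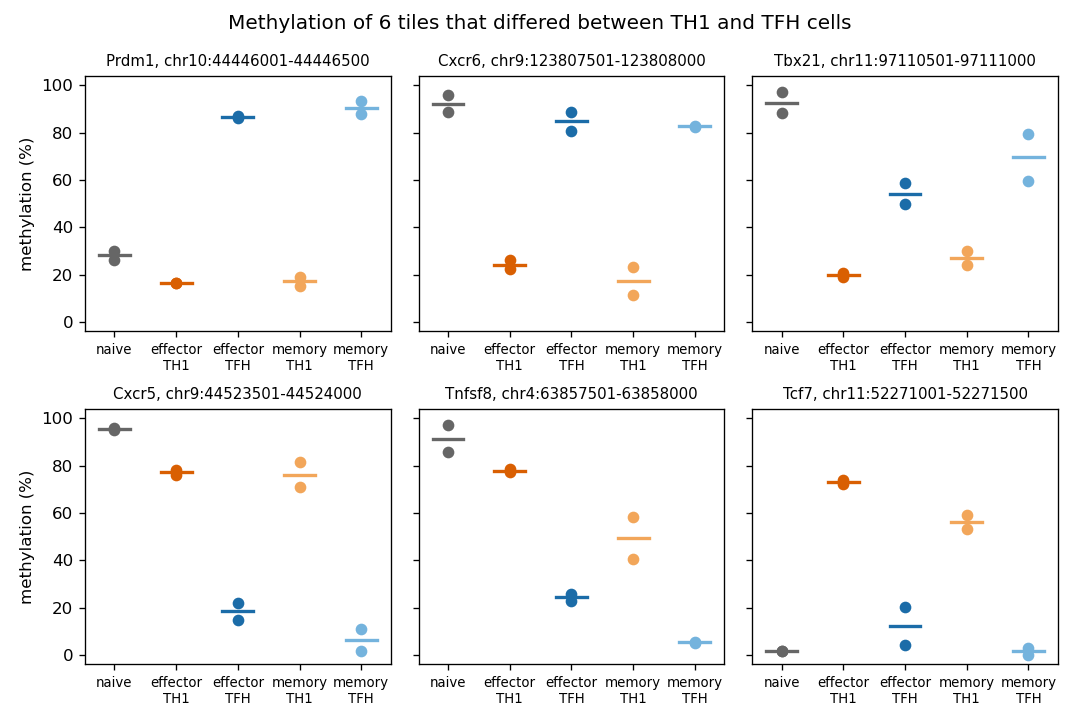
Methylation (y axis, percent) of 6 tiles with differences between TH1 and TFH cells, at Prdm1, Cxcr6, Tbx21, Cxcr5, Tnfsf8 and Tcf7, in the 10 libraries (points) of the 5 groups (x axis), with group means as lines. Prdm1 was at 16.5% in effector TH1 and 86.6% in effector TFH cells, and Cxcr5 at 77.2% and 18.4%.

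Memory TFH cells were compared with memory TH1 cells to ask whether the lineages still differ weeks after infection. Prdm1 stood at 17.2% ± 2.59 in memory TH1 and 90.5% ± 3.94 in memory TFH cells at the tile that differed in effector cells (73.3 points, adjusted p 2.33e-20). Cxcr6 stood at 17.4% ± 8.42 and 82.8% ± 0.225 (65.4 points, adjusted p 1.6e-10). Cxcr5 stood at 76.2% ± 7.54 and 6.48% ± 6.55 (-69.8 points, adjusted p 5.86e-16), and Tcf7 at 56.3% ± 4.14 and 1.52% ± 2.14 (-54.7 points, adjusted p 1.6e-13). These 4 calls held with each library left out, after centring and in both limma fits, and all but Tcf7 held with each tile's own dispersion.

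Id2, whose product supports TH1 over TFH cells, was at 13.4% ± 2.93 in memory TH1 and 53.7% ± 7.14 in memory TFH cells (40.3 points, adjusted p 6.37e-19). A tile inside Il18r1, which is also near Il1rl1, was at 5.17% and 56.3% (adjusted p 1.61e-12). Runx2, a RUNX transcription factor, held 8 tiles called higher in TFH cells, the strongest at 29.6% and 92.3% (adjusted p 1.39e-19), and Atxn1 13, the strongest at 16.8% and 62.7%. Aim2, a sensor of cytosolic DNA, was at 34.8% and 94.2% (adjusted p 1.67e-23) and Dnajc15 at 0% and 46.8%. Lower in memory TFH cells were Scfd2 (76.6% and 13.6%, adjusted p 5.06e-33), Lpp (78.1% and 10.8%, with 17 tiles called lower and 0 higher), Rock1, a kinase of the cytoskeleton (61% and 5.17%), Tspan5 (86.8% and 41%) and Il6ra, a chain of the interleukin 6 receptor (55.1% and 21.1%, adjusted p 1.26e-06). All of these tiles held with each library left out and with centring. Neither limma fit kept Id2, Atxn1, Tspan5 or Il6ra, limma on percents also lost Il18r1 and Dnajc15, and each tile's own dispersion kept only Scfd2 and Lpp.

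Other memory differences at list genes depended on which libraries were in the fit. Tbx21 was at 27% and 69.6% (adjusted p 1.13e-04) but was not called without memory TFH replicate 1, Tnfsf8 (63.6% and 15.7%) and the killer receptor gene Klrk1 (48.9% and 89.2%) not without memory TFH replicate 2. Hif1a (88.2% and 47.8%), Ikzf2 (87% and 53.6%) and Nr4a1, an early gene of receptor signalling (52.1% and 13.2%), were not called without memory TH1 replicate 1. Nr4a3 (35.3% and 72.2%) was not called without memory TH1 replicate 2 or memory TFH replicate 1. Satb1, a chromatin organiser (32.7% and 66.6%), and Foxp1 (34.1% and 70.6%) were not called without memory TH1 replicate 1 or memory TFH replicate 1. Tox held 10 tiles called lower in TFH cells, and its strongest (38.8% and 3.39%) was not called without memory TH1 replicate 1, memory TFH replicate 1 or memory TFH replicate 2. Tet2 (14.1% and 42.5%, adjusted p 0.0296) was lost with centring and without memory TH1 replicate 1, memory TH1 replicate 2, memory TFH replicate 1 or memory TFH replicate 2. Gzmb (20.4 points, adjusted p 0.315), Prf1 (22.1 points, adjusted p 0.147), Ifng (8.61 points, adjusted p 0.236) and Pdcd1 (-20 points, adjusted p 0.107, called with centring and at a coverage of at least 10) were not called.

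The memory comparison called 1670 tiles, 1127 higher and 543 lower in TFH cells, against a median shift of 2.16 points, and all 4 libraries carried 15796. With centring 1373 tiles were called, 506 higher and 867 lower, and 1049 were shared, so that 36.9% were higher with centring and 67.5% without. Without memory TFH replicate 2 the count was 631, and without memory TFH replicate 1, memory TH1 replicate 1 and memory TH1 replicate 2 it lay between 803 and 957. Limma on percents called 84 tiles and limma on logits 61. Of the 41 named called tiles, 36 were called with centring, 11 by limma on percents, 13 by limma on logits and 13 with each tile's own dispersion. TH1 genes held a tile called higher in TFH cells in 14 of 35 cases against 0.962 in random lists (adjusted p 0.001; 23 adjusted over the list alone; 12 with centring, adjusted p 0.001). TFH genes held a tile called lower in 9 of 29 cases against 0.489 (adjusted p 0.001; 14 adjusted over the list alone; 10 with centring, adjusted p 0.001), and naive and central memory genes in 5 of 24 (adjusted p 0.005; 5 adjusted over the list alone; 5 with centring, adjusted p 0.035). Activation genes were called higher in 5 of 20 cases (adjusted p 0.002; 6 adjusted over the list alone; 3 with centring, adjusted p 0.0173). Genes of other helper lineages were called higher in 4 of 20 cases (adjusted p 0.0208; 5 adjusted over the list alone) and T cell identity genes lower in 3 of 18 (adjusted p 0.026; 4 adjusted over the list alone), and neither passed with centring (adjusted p 0.564 and 0.0653). With at least 30 points neither these 2 lists passed nor the activation genes called higher (1 gene, adjusted p 0.611) and the naive and central memory genes called lower (3 genes, adjusted p 0.0836). Tiles called higher that did not pass were held by 4 naive and central memory genes (adjusted p 0.131) and 1 TFH gene, and tiles called lower by 2 activation genes and 2 genes of other helper lineages. Of the other lists 1 gene of the DNA methylation machinery, 1 CD8 T and NK cell marker, 0 B cell markers and 0 myeloid markers held a tile called higher.

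The effector and memory differences between TFH and TH1 cells were set against each other to ask whether lineage differences last. Prdm1, Cxcr6, Cxcr5, Tcf7, Scfd2, Tspan5 and Lpp were called in the same direction at the same tile at both times. Of the 402 tiles lower in effector TFH cells, 176 (43.8%) were called lower in memory TFH cells too, against 0.139 for independent lists, and their median difference was -27.4 points in effector and -24.5 points in memory cells over all 402. Of the 14110 tiles higher in effector TFH cells, 462 (3.27%) were called higher in memory, against 10.1 for independent lists, and their median difference was 24.1 points in effector and 5.86 points in memory cells. With centring the shares were 39.1% and 24.1%. The TFH-higher share was 7.09% without effector TFH replicate 1 and 8.53% without effector TFH replicate 2, 1.58% without either memory TH1 replicate 1 or memory TH1 replicate 2, 1.85% without memory TFH replicate 1 and 1.28% without memory TFH replicate 2. The TFH-lower share was 27.3% without memory TH1 replicate 2 and 25.9% without memory TFH replicate 2, and rose to 55.9% without effector TH1 replicate 2. The sign was kept in 79.8% of the 14512 tiles (95% Wilson interval 79.1 to 80.4), against 66.5% of all tiles with a positive difference in memory, and in 90.8% with centring. Counted from the memory calls, the shares ran the other way. Of 1127 tiles higher in memory TFH cells, 462 (41.0%) were called higher in effector TFH cells. Of 543 tiles lower in memory TFH cells, 176 (32.4%) were called lower in effector TFH cells. A test of the change in the difference itself called 15 tiles, 1 higher and 14 lower in memory. The median change over all tiles was -2.90 points.

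**Figure D4:**
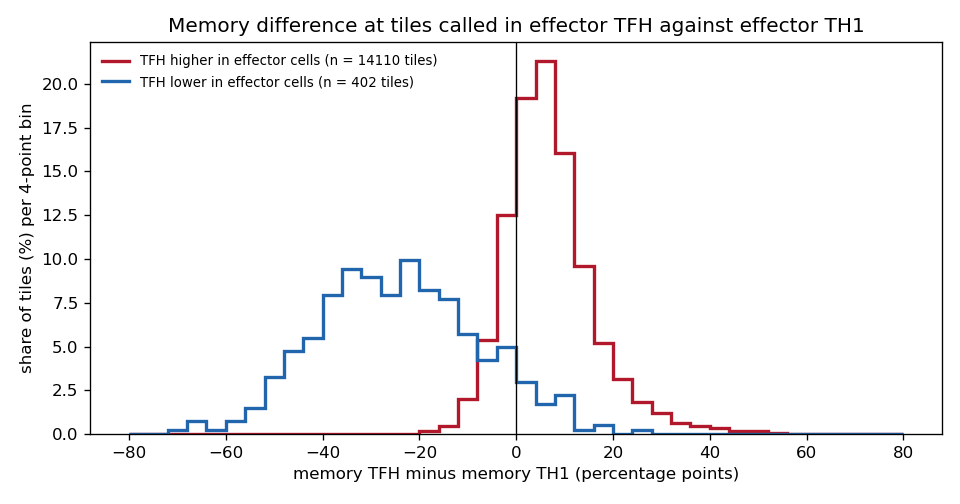
Share of tiles (y axis, percent per bin of 4 points) by their difference between memory TFH and memory TH1 cells (x axis, percentage points), for tiles called higher or lower in effector TFH than in effector TH1 cells. The TFH-lower tiles had a median of -24.5 points in memory and the TFH-higher tiles 5.86.

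Memory TH1 cells were compared with effector TH1 cells to ask what changes within the lineage after the response. Itgb1, an integrin chain of memory cells, fell from 93.4% ± 1.07 in effector to 50.6% ± 2.29 in memory TH1 cells on chromosome 8 from 128689501 to 128690000 (-42.9 points, adjusted p 2.77e-08), with 6 tiles called lower in all. Rnf138, a ubiquitin ligase, fell from 85.3% ± 9.05 to 29.1% ± 4.44 (-56.2 points, adjusted p 6.25e-13) and Scarb2, a lysosomal membrane protein, from 55.2% ± 20.2 to 0% ± 0 (-55.2 points, adjusted p 2.77e-08). Chd7, a chromatin remodeller, rose from 19% ± 2.53 to 55% ± 3.49 (36.1 points, adjusted p 1.23e-07), still below the 94.2% of naive cells. These 4 calls held with each library left out and with centring, but limma on percents kept only Rnf138, and limma on logits and each tile's own dispersion kept none of the 4.

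Osbpl9 rose from 13.4% to 46.1% (adjusted p 1.81e-06) but was not called without effector TH1 replicate 1 or memory TH1 replicate 2, and Jakmip2 rose from 51.8% to 79.7% but was not called without memory TH1 replicate 2. Rora, an orphan nuclear receptor, rose from 28.1% to 57.1% (adjusted p 0.00142), a call lost with centring and without effector TH1 replicate 1 or memory TH1 replicate 2. Ctla4 (32.8% to 57%, adjusted p 0.025) and the Prdm1 tile from 44446501 (50.6% to 72.4%, adjusted p 0.0425) were lost with centring and without any 1 of the effector and memory TH1 libraries (effector TH1 replicate 1, effector TH1 replicate 2, memory TH1 replicate 1 and memory TH1 replicate 2). Actn1, which links actin to the membrane, rose from 19.8% to 43.1% (adjusted p 0.000289), a call lost with centring and without effector TH1 replicate 2 or memory TH1 replicate 1, and Abhd2 and Acot7, lower in memory by -34 and -29.7 points, were lost without the same libraries. Not called were Tcf7 (-16.9 points, adjusted p 0.287), Ifng (26.5 points, adjusted p 0.226), Tbx21 (28 points, adjusted p 0.351), Pdcd1 (30.9 points, from 9.52% to 40.4%, adjusted p 0.106) and Ccr7 (19.4 points, adjusted p 0.14).

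This comparison called 423 tiles, 350 higher and 73 lower in memory TH1 cells, against a median shift of 3.40 points. With centring 127 tiles were called, 18 higher and 109 lower, and 91 were shared, so that 14.2% were higher with centring and 82.7% without. The count was 126 without memory TH1 replicate 2, and 129, 185 and 209 in the fits that left out another TH1 library; limma on percents called 1 tile and limma on logits 0, with 200962 and 139827 tiles at an unadjusted p under 0.05 (173844 by the quasi-F test). Of the 22 named called tiles, limma on percents kept 1, limma on logits 0 and each tile's own dispersion 4, and 14 were called with the title number as a covariate. Within 15796 memory TH1 cells were 3.60 points above effector TH1 cells. No list passed the test (1 TH1 gene higher and 1 lower; 3 and 2 adjusted over the list alone), and with centring the TH1 list did for tiles called lower (3 genes against 0.149, adjusted p 0.008).

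Memory TFH cells were compared with effector TFH cells to ask the same within the TFH lineage. Myo3a, an unconventional myosin, fell from 52.8% ± 12.3 in effector to 28.9% ± 5.26 in memory TFH cells (-24 points, adjusted p 5.38e-10), a call lost without effector TFH replicate 2. Osbpl3 fell from 61.1% ± 6.03 to 32% ± 7.68 (-29.2 points, adjusted p 1.68e-07), a call lost without memory TFH replicate 2. Nars, an aminoacyl-tRNA synthetase, fell from 75.4% to 53.1% (adjusted p 0.00164) and was not called without effector TFH replicate 1 or memory TFH replicate 2. At a coverage of at least 10 the difference at Nars turned to 0.225 points. Asap1 fell from 66.9% to 35.2% (adjusted p 0.00369) and was not called without effector TFH replicate 1, memory TFH replicate 1 or memory TFH replicate 2. Tcf4, an E protein, rose from 70.6% to 98.2% (adjusted p 0.0334) and Rbm20, a splicing factor, from 54.9% to 79.1% (adjusted p 0.00759), and neither was called without effector TFH replicate 2, memory TFH replicate 1 or memory TFH replicate 2. Cxcr5 (-12 points, adjusted p 0.841) and Tcf7 (-10.9 points) were not called, and Tbx21 (-21.1 points, adjusted p 0.0739) was called with centring and with a dispersion prior without trend, but not otherwise. The comparison called 35 tiles, 7 higher and 28 lower, against a median shift of 0.515 points, and 44 with centring, 34 of them shared. The count was 13 without memory TFH replicate 1 and 14 without effector TFH replicate 2, and limma on percents and on logits called 0 and 0 tiles, against 86388 tiles with an unadjusted p under 0.05 by the quasi-F test. Of the 12 named called tiles, each tile's own dispersion kept 1 and the title number as a covariate 6. No list passed the test with or without centring, and within 15796 memory TFH cells were 0.434 points above effector TFH cells. Over each library's own sites the order of the group means turned, with 78.0% in memory and 78.1% in effector TFH cells.

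Memory cells were also compared with naive cells to ask which changes last. Some gains were still present: Tcf7 in TH1 cells (73.1% in effector and 56.3% in memory, against 1.55% in naive cells), Lef1 (70.5% and 85.4% in TFH cells) and Ccr7 (70.4% and 72.6% in TFH cells) stayed above naive cells, as did Znrf1, a ubiquitin ligase (64.2% and 71.3% in TH1 cells, 5.01% in naive cells). Of the 2586 tiles called higher in effector TH1 than in naive cells, 1905 (73.7%) were called higher in memory TH1 cells, and of 187961 called lower, 60343 (32.1%) were called lower. In TFH cells the numbers were 2057 of 2832 (72.6%) and 19614 of 33996 (57.7%). With centring the order was the other way: 55.7% of the tiles called higher and 62.8% of those called lower were called again in TH1 cells, and 69.1% and 80.3% in TFH cells. Effector and memory cells were compared with the same naive libraries, so chance naive values can enter both calls and raise these shares. No expected overlap was computed for them. Memory TH1 cells differed from naive cells at 85928 tiles (82390 lower and 3538 higher) and memory TFH cells at 37875 (34362 lower and 3513 higher). The memory groups shared 2129 tiles called higher and 24499 called lower. The simulation of all 10 libraries from the naive levels shared 0 and 0 called tiles, again fixed in advance by its lack of true differences. The covariance was 46.9 with 9.83 simulated, and part of the excess may come from the shared naive libraries.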

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

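The tests of the number in the titles, of read depth, of the genome-wide difference, of B cells, of myeloid cells and of the held-out naive library were chosen only after the result they concern was seen.

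The TFH-TH1 difference changed from effector to memory cells at 15 tiles by a test of the change itself. Atf2, a stress-activated transcription factor, changed by -27.2 points (chromosome 2 from 73867501, adjusted p 3.43e-06), Spred2, an inhibitor of RAS signalling, by -34.5 points and Nars, whose difference between memory and effector TFH cells turned to 0.225 points at a coverage of at least 10, by -29.8 points (adjusted p 0.000655 each). Scarb2 changed by 46.9 points (adjusted p 0.00643), the 1 tile where the difference rose. These genes were named after their values were seen; 8 of the 15 tiles were among those called higher in effector TFH cells and 0 among those called lower, and 106840 tiles had an unadjusted p under 0.05. The median change over all tiles was -2.90 points, so more tiles lower than higher in memory can come from the genome-wide shift. The test of the change was not run under the alternatives, with centring or with libraries left out. No technical or biological explanation was tested for these 15 tiles.

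The first pattern weighed is the genome-wide loss against naive cells, larger in effector TH1 than in effector TFH cells. Unequal conversion of methylated cytosines predicts about the same loss at dense and sparse methylated sites. Effector TH1 cells lost 1.51 points at CpG-dense sites and 11.5 points at CpG-sparse sites, which argues against it as the cause. Sites chosen as at least 90% methylated say little about unmethylated cytosines left unconverted. For these the mitochondrial reads, methylated in 0.746% to 1.83%, set only a rough upper limit. The number in the titles could not be tested by the within-number differences, since these average to the group difference by design. Each effector group held 1 library of each number, so an effect common to a number cancels in their difference. TFH cells lay 5.81 points above TH1 cells within 15105 and 5.76 points above them within 15796, each of 1 library against 1. Read depth is argued against by a median difference of 5.19 points over sites covered at least 10 times in all libraries. No biological explanation was tested, and the number of cell divisions, which no table measures, stays open.

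The second pattern is that tiles such as those at Cxcr5, Tcf7 and Scfd2, lower in effector TFH cells, were called again in memory more often (43.8%) than tiles higher in effector TFH cells (3.27%), a gap of 40.5 points; leaving out single libraries moved the shares to 25.9% (without memory TFH replicate 2) and to between 1.28% (without memory TFH replicate 2) and 8.53% (without effector TFH replicate 2). Counted from the memory calls the order turned: 41.0% of the 1127 TFH-higher and 32.4% of the 543 TFH-lower tiles were called in effector cells. The same 462 and 176 shared tiles give both sets of shares, which therefore depend on how many tiles were called at each time. The genome-wide difference between the effector groups as the whole cause stays open. With centred libraries the gap was 14.9 points (24.1% with an interval of 20.8 to 27.8 against 39.1% with 35.4 to 42.8). Centring removed most of the gap, but it sets libraries to a common level, while the genome-wide difference varied with CpG density. At sites with 1 to 3 CpG sites within 250 bp, effector TH1 cells stood at 71.4% and effector TFH cells at 79.3%. At sites with 25 or more the levels were 51.4% and 52.3%. The remaining gap therefore cannot decide, and its intervals do not cover the spread between libraries. After weighting to the sizes of the TFH-lower tiles, the TFH-higher share was 7.88% (SE 0.384). This lay below the lower limit of 39.0% of the TFH-lower share, which argues against smaller observed differences alone. The sizes were not centred, and the median shift of 5.14 points raises them in TFH-higher and reduces them in TFH-lower tiles. Smaller differences beyond that shift therefore stay open. The genome-wide difference and smaller differences acting together were not tested and stay open. So does a recovery of methylation in memory TH1 cells that is specific to part of the genome.

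The third pattern is the gain of methylation against naive cells at Tcf7, Lef1, Ccr7 and other naive and T cell identity genes; a mixture would give the median gained tile only if at least 43.2% of the DNA in effector TH1 and 42.3% in effector TFH samples came from other cells. B cells as the source of the gains are argued against by 3 of 12 B cell markers in effector TH1 cells (Pax5, Ebf1 and Blk) and 3 of 12 in effector TFH cells with a tile that fell by that share (5 and 4 at the lower quartile of the shares), and their lowest tiles stood at 21.5% ± 1.26 in naive, 20% ± 1.33 in TH1 and 23.2% ± 1.06 in TFH cells (n = 2). Myeloid cells as the source of the gains in effector TFH cells are argued against by 2 of 12 markers (4 at the lower quartile), but in effector TH1 cells they stay open, with 1 of 12 at the median and 6 at the lower quartile; their lowest tiles fell from 44.4% ± 1.96 to 34.1% ± 2.18 in TH1 and 38.5% ± 0.942 in TFH cells, and smaller shares of either cell type were not excluded. Chance values of the shared naive libraries are argued against by the gains against the naive library held out of the calls, whose smallest lower quartile was 19 points. An active change of these loci in responding cells and selection of naive cells that already carried it also stay open, as untested.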

How the results depend on the processing

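The alternatives with each tile's own dispersion and with a coverage of at most 100, and the list tests with centred libraries, were chosen only after the result was seen; the others were planned. The share of effector TFH-TH1 tiles with the same sign in memory was 79.8% and stayed between 74.5% and 100% in the alternatives run.

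With the replicate number as a block, counts in the order effector TH1 against naive, effector TFH against naive, effector TFH against TH1, memory TFH against TH1, memory against effector TH1 and memory against effector TFH were 190579, 36562, 14009, 1619, 350 and 37, all within 1.5 times the main counts; nested in the time point, the paired block gave 14020 and 1664 tiles for the TFH-TH1 comparisons. In the same order, a difference of at least 10 points gave 604589, 85475, 33108, 2113, 705 and 49 tiles and a share of 77.9%, and at least 30 points gave 37865, 13644, 2098, 807, 131 and 14 with 86.8%. Tiles with at least 5 sites gave 33354, 9916, 3123, 790, 170 and 23 with 84.2%, and sites covered at least 10 times gave 24884, 3869, 2589, 294, 148 and 8 with 81.8%, in both cases with fewer tiles tested (566269 and 249485). Nars in memory against effector TFH cells turned to 0.225 points at that coverage; the cause was not tested. Limma on percents gave 187571, 16373, 467, 84, 1 and 0 with 85.2%, and limma on logits gave 39, 61, 0 and 0 for the last 4 with 100%; for the 0 of memory against effector TFH cells by limma on percents 80868 tiles had an unadjusted p under 0.05. Each tile's own dispersion where larger gave 19403, 4281, 484, 42 and 2 for all but the first with 81.7%. Centring gave 29474, 18551, 1230, 1373, 127 and 44 with 90.8%. Each library's own sites gave 771 and 93 tiles for the last 2 with 78.8%, fits without the trend and robust options 53 for the last with 80.4%, and tiles of 1000 bp 739 and the title number as a covariate 255 for memory against effector TH1 cells. The cause was not tested for these changes, except that fewer or more tiles were tested.

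With each library left out in turn, effector TFH against TH1 gave 3035 to 15094 tiles, memory TFH against TH1 631 to 1724, memory against effector TH1 126 to 472, memory against effector TFH 13 to 42 and the share 74.5% to 84.1%. Genome-wide means over each library's own sites were 82.5% in naive, 72.0% in effector TH1, 78.1% in effector TFH, 77.0% in memory TH1 and 78.0% in memory TFH cells, and means over tiles 76.5%, 82.0%, 80.1% and 82.5% in the last 4. Of 120 list tests 26 passed, 30 with 20000 bp on both sides (23 in both) and 26 with at least 30 points (17 in both). Of the named called tiles, those also called with centring were 57 of 62, 60 of 61, 28 of 52, 36 of 41, 12 of 22 and 12 of 12 in the order above. Promoters, motifs, GC matching and exons or introns were not run, since they need a genome or gene strands. At 52 reads per tile and library, 33.3% of simulated 20-point differences were called, so differences near the minimum are often missed. A call needs an observed difference of at least 20 points, which limits this share at any depth. Depth was not varied, so its part is unknown.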

Other observations

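The values below were chosen after the data were examined, and no explanation is offered for them.

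The loss of methylation was larger where CpG sites were sparse. Sites with 1 to 3 CpG sites within 250 bp stood at 86.1% ± 0.546 in naive, 71.4% ± 0.0801 in effector TH1 and 79.3% ± 0.127 in effector TFH cells (n = 2), while sites with 25 or more stood at 53.2% ± 0.556, 51.4% ± 0.405 and 52.3% ± 0.618. In windows of 100000 bp without a protein-coding gene the median difference from naive cells was -13.2 points in effector TH1 and -5.71 points in effector TFH cells, and in memory it was -8.72 and -5.08 points. Windows wholly inside gene spans were close to this, at -12.2 and -5.35 points in effector cells, while windows partly in gene spans lay at -11.3 and -9.03 points in effector TH1 cells (under and over 50% of the window). Inside gene spans naive cells stood at 87.1% and effector TH1 cells at 77.4%, and outside them at 85.9% and 73.9%. The tiles called in effector TH1 cells split by place: 75.9% of those higher than naive and 44.5% of those lower lay in or near a protein-coding gene, against 51.9% of all tiles.

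On the X chromosome, fitted apart with sex as a covariate over 17363 tiles, Sh2d1a, which encodes the TFH adaptor SAP, fell from 64.2% ± 13.6 in naive cells to 35.6% ± 31.5 in effector TH1 (adjusted p 0.00754) and 37.6% ± 19.6 in effector TFH cells (adjusted p 0.0354). Gpm6b, a membrane protein gene, fell from 75.3% ± 8.11 to 49.3% ± 7.84 (adjusted p 0.0155) and 45.6% ± 11.4 (adjusted p 0.0348). The 2 libraries of a group, 1 male and 1 female, lay far apart at Sh2d1a, and no library was left out in turn on X. Foxp3, Cd40lg and Il2rg held no called tile in these comparisons. Effector TH1 cells differed from naive cells at 2270 X tiles, effector TFH cells from naive cells at 215 and effector TFH from TH1 cells at 111, all of these 111 higher in TFH cells. Memory against effector TFH cells gave 0 X tiles by the quasi-F test, with 904 at an unadjusted p under 0.05. Male and female libraries differed at 11 autosomal tiles, 3 higher and 8 lower in males.

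The lowest tile of each gene averaged 51% in naive, 29.1% in effector TH1 and 36.6% in effector TFH cells over the CD8 T and NK cell markers, 44.4%, 34.1% and 38.5% over the myeloid markers and 4.56%, 3.30% and 4.89% over the T cell identity genes. Among other-cell genes, single tiles with large falls in effector TH1 cells lay at Ebf1 (94.5% to 31.2%), Pax5 (55.6% to 0%) and Blk (83% to 27.3%). Others lay at Itgam (55.4% to 21.1%), Csf3r (51.8% to 29.6%) and Spi1 (91.5% to 53.2%). Of these Ebf1 and Pax5 had 389 and 111 tiles to choose from, and Blk and Itgam 36 and 43. Most markers fell less: relative to naive cells the largest fall was 18.2% at Cd22, 21% at Cd79b, 13.7% at Cd14 and 4.3% at Cebpb, with a median of 26.3% over the B cell and 34.9% over the myeloid markers. B cell markers held a tile called lower in 8 of 12 cases against 9.3 in random lists.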
